A study of Gallus gallus with 6 samples.

How the data were processed

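RNA sequencing was analysed for 6 libraries of skeletal muscle from broiler chickens (Gallus gallus) aged 180 days, 3 of soleus (a leg muscle) and 3 of pectoralis major (the breast muscle). Per the series description, tissue was collected after slaughter. Per the labels, total RNA was extracted with TRIzol and libraries were made with a VAHTS Universal V6 kit. Per the submitters' processing notes, HISAT2, HTSeq, Cufflinks and R 3.2.0 are the tools and GRCg6a is the genome build; versions of the other tools, and whether strand was used in counting, are not given in the sources used here. The values are FPKM (fragments normalized to the length of the gene and to the total of the library), computed by the authors and deposited as 1 table for all libraries, with symbols, gene numbers and annotation terms, per the file headers. Small RNA data, which the series title mentions, were not used here.

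The table held 18239 genes, of which 15322 were listed as protein coding and 2917 as non-coding. All 18239 gene numbers matched the gene table of assembly GRCg7b, which differs from the build in the processing notes, so no coordinates are given. In the table, 10 symbols read as dates, and these were restored from the gene numbers. Genes that share reads with close copies, such as the myosin heavy chain and histone clusters, are uncertain where the counting could split reads between them.

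Depth was worked out from the steps of the FPKM values. In each library, a gene's values are whole multiples of the value of 1 fragment, and whole fragments reproduced 100.0% of the 94897 values above 0 within a relative tolerance of 1e-06. The library totals from these steps were 38534335, 39079981 and 39035816 fragments in soleus libraries 1 to 3 and 36309597, 37085046 and 37123092 in pectoralis major libraries 1 to 3. At this depth, 1 fragment of a gene of 1 kilobase was worth 0.0256 to 0.0275 FPKM. On simulated fragments of 17865 genes, the step method returned all 6 fragment numbers for 96.8% of genes.

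The main test was limma 3.58.1 in R 4.3.3 (linear model with a variance trend, two-sided) on log2(FPKM + 1), for genes with an FPKM of at least 1 in at least 3 of the 6 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. All differences are soleus minus pectoralis major on the log2(FPKM + 1) scale, which understates the change of low genes, and means are given ± SD with n = 3 libraries per muscle. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the table and drew the figures. Gene lists were tested with limma's camera (preset inter-gene correlation 0.01), adjusted over the 21 lists with at least 5 tested members. Camera compares a list with the other genes, while fry, an alternative, compares it with no change. Symbols fixed for a list and not found in the table were left out, which left 17 of 21 slow contractile, 18 of 24 fast contractile, 31 of 39 glycolysis and glycogen and 66 of 93 respiratory chain symbols. Some of those left out, such as ATP5F1B beside ATP5B, were other names of genes that were found, and whether the rest are in the table under another name was not checked. Annotation terms with 10 to 300 tested genes were tested with a one-sided Fisher's exact test among genes at least 2-fold higher and, apart, at least 2-fold lower, with the tested genes as background. The scripts were tested on simulated data of 9616 genes with 200 genes changed. For soleus against pectoralis major so simulated, limma called 93% of genes changed 4-fold, 72.5% of those changed 2-fold and 23.8% of those changed 1.5-fold, and 0.05% of unchanged genes. With the replicate block, on the same data, which were simulated without pairing, these were 87.7%, 31.2%, 0% and 0.07%. In the real comparison 57.3% of tested genes were called, so the adjusted threshold was less strict there than in the simulation. These rates check the scripts and do not give the sensitivity of the real comparison.

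The gene lists, the tests, most alternatives and the rule for named genes were fixed before the data were examined. The rule named, per direction, the 8 genes with the largest log2 difference among those called, without overlap between muscles, with a mean FPKM of at least 10 in the higher muscle and a symbol that is not a locus name. It also named, per list, up to 4 called members with the largest difference and the member with the highest mean FPKM, every called fibre type regulator with at least a 2-fold difference, and any gene that a count of 5 or fewer refers to. Some genes that the rule names are not reported here. Other list members are named only as values, and genes outside the rule are said to be chosen after their values were seen. The lists cover contractile proteins, fibre type regulators, energy metabolism, excitation, meat quality traits (lipid storage, extracellular matrix, proteolysis, purines and carnosine), markers of other cell types, and immediate early and heat shock genes.

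The labels number the libraries 1 to 3 in both muscles without saying that a number marks a bird. Deviations from the muscle means correlated across tested genes at r = 0.398, 0.445 and 0.367 for equal numbers and at -0.301 to -0.128 for unequal numbers. Deviations sum to 0 within a muscle, so the negative values follow from the positive ones and are no separate evidence. The numbers were taken to pair the libraries, from the data and not from the labels, whether by bird or by handling. The main test was fixed without this pairing, so its p-values ignore it, and the paired fit is an alternative (the replicate block). The W-linked gene HINTW lay at 0.0658 to 0.374 FPKM in all 6 libraries, and ATP5F1AW, also W-linked, at 88.7 to 102.3 FPKM in soleus and 40.7 to 44.1 in pectoralis major. As the first was low and the second high in all 6, neither told the libraries of a muscle apart, and they gave no further check of the pairing. No libraries of 1 muscle agreed within sampling noise.

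The alternatives chosen beforehand were a pseudocount of 0.1, no filter on low values, a mean FPKM of at least 5, 3 other scalings (median ratio, total without the 50 most abundant genes, quantile), no variance trend, the replicate number as a block, leaving out each library, an estimated inter-gene correlation, fry for the lists, and other thresholds for the terms. Scaling to the total without mitochondrially encoded genes, and limma's voom on the recovered fragments, were chosen after seeing the data. The first component's share of variance was taken as moved when it left the reported value by more than 0.99 percentage points, the SD of the leave-one-out values; this tolerance was set after the values were seen.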

Results

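Transcript levels were compared between soleus and pectoralis major of 180-day-old broilers, muscles that the series describes as very different in fibre type make-up, in 3 libraries each. Library totals were 38534335 to 39079981 fragments in soleus and 36309597 to 37123092 in pectoralis major (n = 3 each). An FPKM of at least 1 was reached by 9725 ± 112 genes in soleus and 8689 ± 133 in pectoralis major. Mitochondrially encoded genes took 34.2 ± 3.43% of all FPKM in soleus and 14.7 ± 1.41% in pectoralis major. The first principal component held 82.8% of the variance and parted the muscles, and Pearson's r over tested genes was 0.980 to 0.987 within a muscle and 0.880 to 0.893 between muscles. The labels do not say whether the libraries of a muscle came from separate birds, so p-values measure only the spread between these samples, which may be technical.

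The comparison asked which genes differ between muscles of contrasting fibre type. Most slow contractile genes tested, with the exception of TNNC1, and most genes of fatty acid use were higher in soleus, as was myoglobin, while of 31 genes of glycolysis and glycogen, 15 were lower and 8 higher. The fast contractile genes were split, with the myosin heavy chain MYH1E lower and MYH1A, MYH1B, MYH1C and MYH1G higher. The higher ones had means of only 80.6 (MYH1B) to 465.2 FPKM (MYH1C) in soleus, far below that of MYH1E in pectoralis major. MYL3, a slow myosin light chain (gene number 396067), had 4688 ± 1218 FPKM in soleus and 0.116 ± 0.116 in pectoralis major, and MYH1E, a fast myosin heavy chain (gene number 427788), had 4.31 ± 2.96 and 4823 ± 73.4. Of 9616 genes tested, 3844 were higher and 1670 lower in soleus, and 908 and 529 of these differed at least 2-fold. The groups did not overlap for 64.9% of genes, where chance gives 10%. Of the named genes that passed the test, only TAGLN overlapped. This adds no support, since only 107 of all 5514 calls overlapped and the rule required no overlap for the genes of largest difference. Of the calls, 69.7% were higher in soleus, a split that depended on the scaling and the filter: it was 41.7% under median-ratio scaling, 48.1% under quantile normalization, 81.7% with mitochondrially encoded genes left out of the totals and 55.4% with a mean FPKM of at least 5. The median log2 difference of all genes was 0.26 as deposited, -0.04 under median-ratio scaling and 0.44 without mitochondrially encoded genes.

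The counts adjusted over the list alone were the same as those over all genes for every list below unless given. As background to these counts, 3844 of all 9616 tested genes rose in soleus and 1670 fell, and both numbers moved with the scaling. A list with shares near these is not set apart by its counts. Of 15 slow contractile genes tested, 12 rose in soleus and 1 fell (camera adjusted p = 7.47e-07, and adjusted p = 0.165 with an estimated correlation). Large differences were also those of MYL10, a myosin light chain (log2 difference 10.70), TNNI1, slow troponin I (10.33), MYOZ2 (9.26), MYH7B, a slow myosin heavy chain (9.05), and the stretch-responsive genes ANKRD2 (8.70) and CSRP3 (8.65). MYL2 had 890.9 ± 260.3 FPKM in soleus and was listed at 0 in all pectoralis major libraries. TNNC1, the troponin C of slow and cardiac muscle (gene number 396032), went the other way, with 4101 ± 1052 FPKM in soleus and 17408 ± 2476 in pectoralis major (log2 difference -2.11 ± 0.21 SE, limma adjusted p = 9.42e-05). CASQ2 (0.22) and ANKRD1 (-1.11) did not pass the test. ANKRD1 passed it with the replicate block (adjusted p = 0.000255) and without soleus library 3 (0.0217) or pectoralis major library 1 (0.0279), and CASQ2 without pectoralis major library 1 (0.0489) or with mitochondrially encoded genes left out of the totals (0.0304), while its difference was -0.17 under median-ratio scaling.

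**Figure D1:**
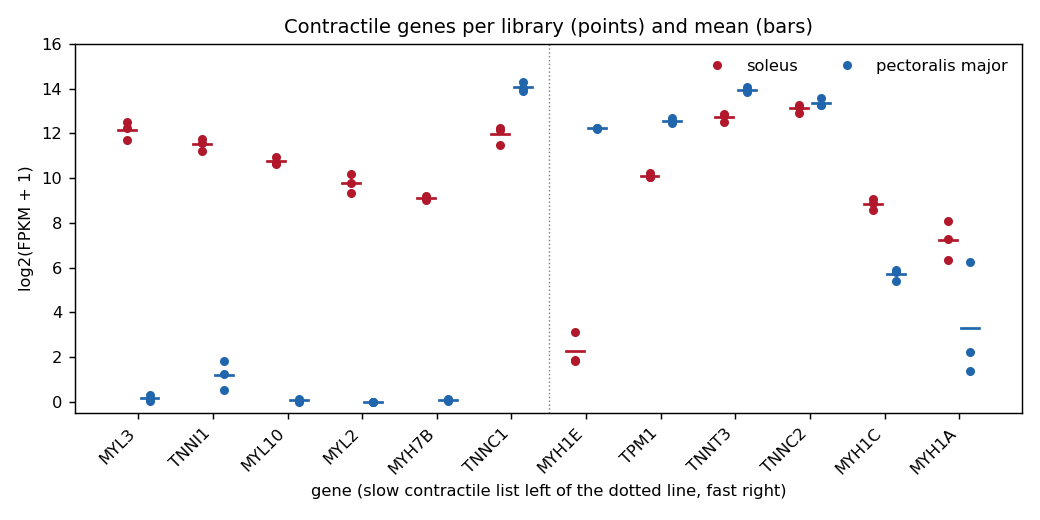
Each point is a library's log2(FPKM + 1) of a contractile gene and each bar the mean of 3 libraries, red for soleus and blue for pectoralis major. MYL3 lies far higher in soleus and MYH1E far higher in pectoralis major, and TNNC1, of the slow list, also lies higher in pectoralis major (17408 against 4101 FPKM).

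Of 24 fast contractile symbols fixed, 18 were in the table (MYLPF, ATP2A1, CASQ1, MYBPC2, ACTN3 and MYH2 were not found), and of the 17 genes tested, 7 rose in soleus and 8 fell, so these counts describe only part of the fast genes. The list's mean (0.12), median (-0.25) and test differed in sign: camera placed it lower in soleus (adjusted p = 0.0445), a call lost with an estimated correlation (adjusted p = 0.556) and with the replicate block (adjusted p = 0.0792). It was also lost without pectoralis major library 1 (adjusted p = 0.185) or 3 (0.0615), with a pseudocount of 0.1 (0.0508), with a mean FPKM of at least 5 (0.156), under median-ratio scaling (0.435) and quantile normalization (0.434), and without the 50 most abundant genes in the totals (0.0917). MYH1E (-9.96), TPM1 (-2.46) and TNNT3, fast troponin T (-1.22), were lower in soleus. The fast myosin heavy chains MYH1B (4.05), MYH1G (3.96), MYH1A (3.94) and MYH1C (3.15) and the calcium buffer PVALB (3.73) were higher. Their soleus means were 80.6 (MYH1B), 95.6 (MYH1G), 166.8 (MYH1A), 465.2 (MYH1C) and 15.8 FPKM (PVALB). MYH1E had a mean of 4823 FPKM in pectoralis major. MYH1A did not pass without soleus library 1 (adjusted p = 0.0562), and its difference was 2.98 without pectoralis major library 2 and 5.42 without library 3; that of MYH1B was 4.91 without pectoralis major library 1. These heavy chain genes are close copies, so the split of fragments between them is uncertain. TNNC2, fast troponin C, had 8954 ± 1099 and 10679 ± 1293 FPKM and did not pass as deposited, but passed as lower in soleus under median-ratio scaling (adjusted p = 0.0135) and without the 50 most abundant genes in the totals (0.0469). MYH1D had 4.36 ± 3.08 and 4.11 ± 5.37 FPKM and did not pass.

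Outside the lists, the rule named IGFN1 (0.0313 ± 0.0204 FPKM in soleus and 170.6 ± 31.4 in pectoralis major), BPGM, an enzyme of 2,3-bisphosphoglycerate metabolism (log2 difference -5.10), MYBPHL (-4.95), FRMD5 (-4.56) and NRGN (-4.37) as lower in soleus. The difference of MYBPHL was -4.25 without soleus library 3.

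Of 39 symbols of glycolysis and glycogen, 31 were in the table (ALDOA, PKM, ENO3 and PYGM were among those not found), and of these 15 fell in soleus and 8 rose (camera adjusted p = 8.17e-06, and adjusted p = 0.346 with an estimated correlation). LDHA, the muscle lactate dehydrogenase, had 641.4 ± 169.1 FPKM in soleus and 9906 ± 893 in pectoralis major. GPD1 (-4.02), PGM1 (-3.90) and PGAM1 (-3.47) also fell, and GAPDH, the most abundant member, had 13157 ± 2708 and 59547 ± 3613 FPKM.

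Of 29 genes of fatty acid uptake and oxidation, 23 rose in soleus and 1, UCP3 (-1.93), fell (camera adjusted p = 1.22e-05, and adjusted p = 0.319 with an estimated correlation). PDK4, which restrains pyruvate oxidation, rose by a log2 difference of 4.99, the fatty acid transporter CD36 by 3.81, the lipase PNPLA2 by 3.52 and PLIN5 by 3.34, and FABP3 had 1870.5 ± 318.5 FPKM against 265.04 ± 52.3. Of 20 adipocyte genes 17 rose (median 1.56), and of 15 endothelial genes 14 (median 0.84). CD36 and PNPLA2 are also expressed in such cells, so a change within the fibres was not separated from a larger share of these cells in soleus. All 13 mitochondrially encoded genes rose, the largest differences being those of COX3 (1.73), ND2 (1.59), COX1 (1.54) and COX2 (1.5) (camera adjusted p = 0.00023, and adjusted p = 0.422 with an estimated correlation). Of 66 nuclear genes of the respiratory chain, 37 rose, led by COX6A1 (2.70), COX7A2 (1.36), NDUFV1 (1.20) and NDUFA5 (1.19), and UQCR10 (-0.43) fell (camera adjusted p = 0.00195, and adjusted p = 0.556 with an estimated correlation). UQCR10 did not pass without soleus library 1 (adjusted p = 0.0822), soleus library 2 (0.0514) or pectoralis major library 3 (0.0785), or without mitochondrially encoded genes in the totals (0.242). The call of this list was lost under median-ratio scaling (adjusted p = 0.148), where ATP5B, the most abundant member (0.79), did not pass either. Of 22 genes of the tricarboxylic acid cycle and pyruvate entry, 13 rose, with IDH2 (1.96), MPC2 (1.04) and OGDH (246.2 ± 33.5 FPKM in soleus and 122.2 ± 14.6 in pectoralis major) among them (camera adjusted p = 0.0336, and adjusted p = 0.556 with an estimated correlation), and the call was lost under median-ratio scaling (adjusted p = 0.3), without the 50 most abundant genes in the totals (0.0757) and without soleus library 3 (adjusted p = 0.0613), pectoralis major library 2 (0.0577) or pectoralis major library 3 (0.071). MDH2 had 634.2 ± 26.3 and 663.6 ± 30.6 FPKM and did not pass as deposited, but passed as lower in soleus under median-ratio scaling (adjusted p = 0.0221) and quantile normalization (0.0336).

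**Figure D2:**
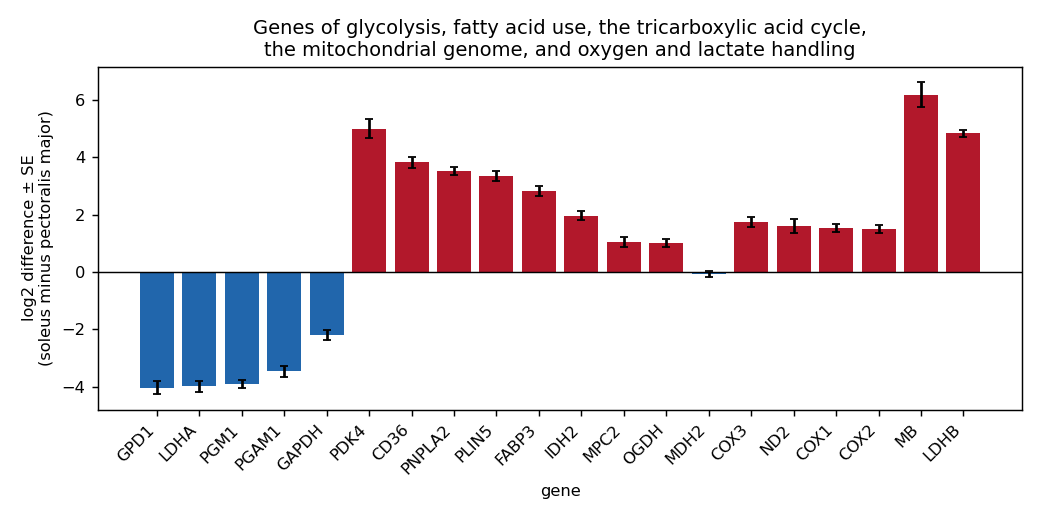
Bars give the log2 difference on the log2(FPKM + 1) scale, soleus minus pectoralis major, with its standard error, for genes of 5 metabolic lists. The glycolytic genes lie below 0 (GAPDH at -2.20), and the others above it except MDH2 (-0.07), which did not pass the test and lies above 0 (0.17) without mitochondrially encoded genes in the totals.

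Of 10 genes of oxygen and lactate handling, 8 rose and CKMT2 (-0.55) fell (camera adjusted p = 0.0228, and adjusted p = 0.422 with an estimated correlation). CKMT2 did not pass without soleus library 1 (adjusted p = 0.0571) or 2 (0.0978) or pectoralis major library 1 (0.111) or 3 (0.0677). Myoglobin, MB, had 4560 ± 667 FPKM in soleus and 74.1 ± 52.7 in pectoralis major, and LDHB (4.83), VEGFA (1.70) and CA4 (1.42) followed. Of 18 genes of excitation and calcium release, 8 rose and 6 fell, and the list was not called (camera adjusted p = 0.41). Its median was -0.11 and its mean 0.55, and fry, which tests against no change, placed it higher in soleus. PLN, which restrains the calcium pump, had 303.4 ± 70.8 FPKM in soleus and 0.246 ± 0.0707 in pectoralis major. CAMK2A (2.77) and CACNA1S (2.47) were also higher, and SLN (-1.34) was lower.

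Of 47 fibre type regulators, 21 rose and 10 fell (22 and 10 when adjusted over the list alone), and the list was not called (camera adjusted p = 0.923). RCAN1, a target of calcineurin (2.32), NR4A3 (2.14), PROX1 (1.53), MSTN, myostatin (1.34), KLF15 (1.27), MYOD1 (73.4 ± 24.4 FPKM in soleus and 30.6 ± 10.4 in pectoralis major), TBX15 (1.24), PPARD (1.17), PPARGC1A (1.12) and ESRRB (1.02) rose at least 2-fold. PRKAG3, a subunit of AMP-activated kinase (-3.04), the homeobox factor SIX2 (-2.17) and EYA4 (-1.18) fell. NR4A3 had 15.8, 6.59 and 47.5 FPKM in soleus libraries 1 to 3, and its difference was 2.78 without soleus library 2 and 1.44 without library 3.

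Of 20 genes of purine nucleotide and carnosine metabolism, 9 fell and 5 rose (camera adjusted p = 0.00797, and adjusted p = 0.422 with an estimated correlation). CARNS1, carnosine synthase, fell by 3.11 on the log2 scale, GART by 3.03, AMPD1, the muscle AMP deaminase, by 2.97 and AK1 by 2.84. SLC6A6 (1.61), ATIC (1.26), AMPD3 (1.09), CSAD (0.81) and AMPD2 (0.48) rose. Of 20 adipocyte and lipid storage genes, 17 rose and ME1 (-2.07) fell (camera adjusted p = 0.00023, and adjusted p = 0.165 with an estimated correlation). THRSP (2.89), PLIN1 (2.88), CIDEC (2.78) and PLIN4 (2.70) were in front. Of 33 extracellular matrix genes, 16 rose (15 when adjusted over the list alone) and NID1 (-1.26) fell. The list was not called (camera adjusted p = 0.0585, and adjusted p = 0.628 with an estimated correlation). It was called at the preset correlation with the replicate block (adjusted p = 0.0254), but not with the block and an estimated correlation (adjusted p = 0.658). It was also called without soleus library 2 (adjusted p = 0.0228) or pectoralis major library 3 (0.00161), with no filter (0.0336) or a mean FPKM of at least 5 (0.00926), under median-ratio scaling (0.0458) and quantile normalization (0.000846), without the 50 most abundant genes in the totals (0.048) and with voom (0.0475), and not in the other settings of camera. Against no change instead of against other genes, a different question, fry gave an adjusted p of 0.0265. FMOD (2.72), BGN (1.94), MFAP5 (1.85) and COL12A1 (1.81) rose, and SPARC had 127.6 ± 17.5 and 81.5 ± 39.7 FPKM and did not pass (adjusted p = 0.0526), but passed with the replicate block (0.00331), without pectoralis major library 3 (0.0014), without mitochondrially encoded genes in the totals (0.013) and with voom (0.0434). Of 19 genes of proteolysis, 8 rose (9 when adjusted over the list alone) and 5 fell, with camera (adjusted p = 0.679) and the median (0.43) differing in sign. CAPN3 (-1.77), MAP1LC3B (-1.13), PSMD4 (-0.76), FBXO40 (-0.60) and PSMB5 (-0.56) fell, and CAPN2 (1.68), CAST, the calpain inhibitor (1.47), CTSK (1.42) and SQSTM1 (0.70) rose.

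Among the lists of other cell types, those of endothelial cells, leukocytes, Schwann cells and tendon cells were called higher in soleus at the preset correlation and not with an estimated one, and those of smooth muscle and satellite cells were not called. Of 15 endothelial genes, 14 rose in soleus, among them EGFL7 (1.27), CLDN5 (1.18), KDR (1.11), PECAM1 (1.05) and VWF (0.72) (camera adjusted p = 0.00359, and adjusted p = 0.422 with an estimated correlation). Of 16 leukocyte genes, 11 rose, with LY86 (1.47), SPI1 (1.20), C1QB (1.10), C1QC (1.00) and CD74 (0.84) (camera adjusted p = 0.0296, and adjusted p = 0.62 with an estimated correlation; 0.0645 without pectoralis major library 2). All 6 Schwann cell genes tested rose, among them MBP (0.99), SOX10 (0.95) and PMP22 (0.67) (camera adjusted p = 0.0359, and adjusted p = 0.556 with an estimated correlation; 0.0645 and 0.0556 without pectoralis major library 2 or 3, and 0.0619 without mitochondrially encoded genes in the totals). The 5 tendon genes CHAD (2.32), CILP2 (2.23), COMP (1.75), SCX (1.55) and TNMD (1.5) rose (camera adjusted p = 0.0101, and adjusted p = 0.436 with an estimated correlation). Of 9 smooth muscle and pericyte genes, 8 rose, with SMTN (2.09), ACTA2 (1.20), MYH11 (1.19), TAGLN (0.98) and RGS5 (0.91), and MYOCD (-0.89) fell; the list was not called (camera adjusted p = 0.122, and adjusted p = 0.624 with an estimated correlation). It was called at the preset correlation with the replicate block (adjusted p = 0.0299), under quantile normalization (0.0329) and with a mean FPKM of at least 5 (0.0137), but not with the block and an estimated correlation (adjusted p = 0.488), and fry, against no change, gave 0.0233. TAGLN did not pass without soleus library 1 (adjusted p = 0.146) or 3 (0.111) or pectoralis major library 2 (0.0991). Of 6 satellite cell genes, CD34 (1.14), HEYL (0.96) and SPRY1 (0.55) rose, the list was not called (camera adjusted p = 0.259), and HES1 had 20.1 ± 6.68 and 21.5 ± 12.8 FPKM. Of 4 erythrocyte genes, 0 passed by limma, 0 had an unadjusted p under 0.05 and 0 passed with voom, and HBA1 had 431.5 ± 190.1 and 334.9 ± 102 FPKM. Of 21 immediate early and heat shock genes, 10 rose and 2, DNAJA1 (-1.57) and HSPA8 (-0.39), fell, and the list was not called (camera adjusted p = 0.426). HSPA8 did not pass without soleus library 1 (adjusted p = 0.0652) or pectoralis major library 2 (0.0655). HSPB7 (2.83), FOS (2.15) and EGR1 (1.5) rose, and HSPB1 had 4083 ± 1004 and 3749 ± 401 FPKM.

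**Figure D3:**
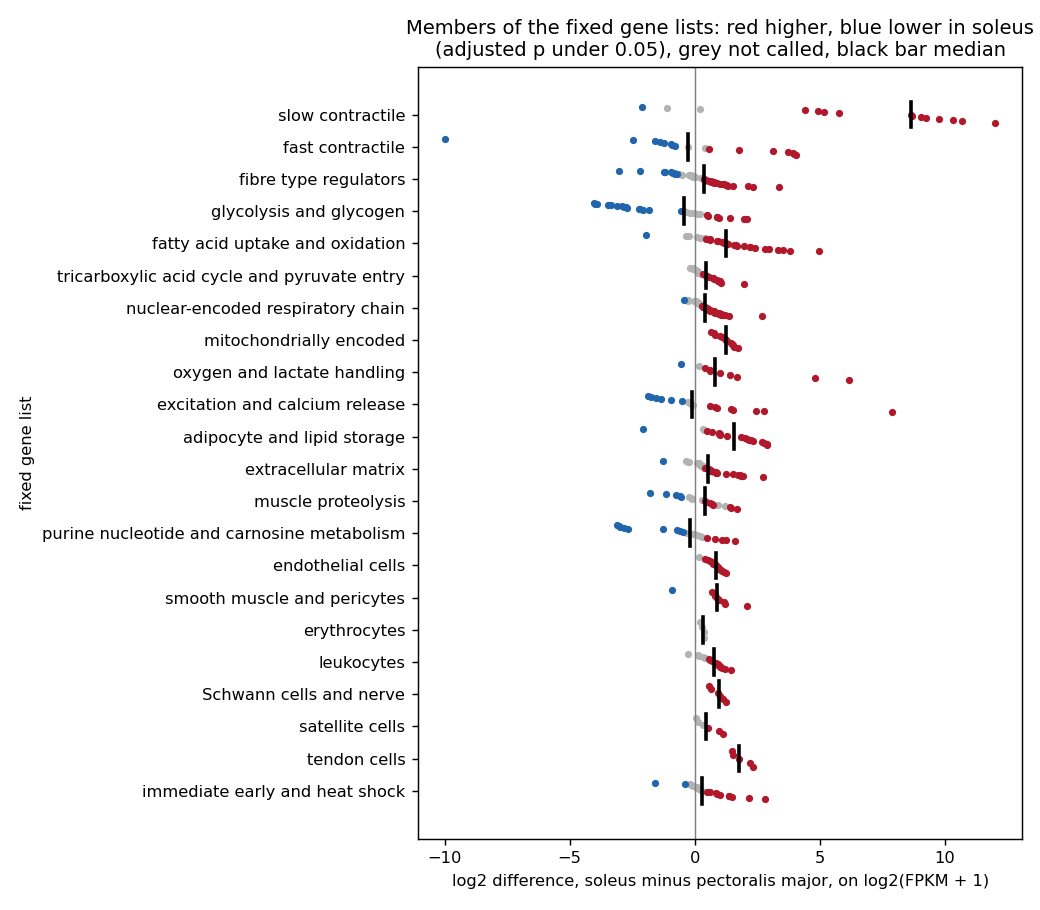
Each point is a tested member of a fixed gene list, placed by its log2 difference, soleus minus pectoralis major, on the log2(FPKM + 1) scale; red and blue points were called and the black bar is the list's median. Slow contractile genes reach the largest values (MYL3 at 12.01), and fast contractile genes lie on both sides of 0.

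Of 1335 annotation terms tested, 41 were over-represented among genes at least 2-fold higher in soleus and 8 among those at least 2-fold lower (Fisher's exact test, one-sided, adjusted). Terms were tested only on calls from the values as deposited. Under median-ratio scaling the at least 2-fold calls were 494 higher and 1039 lower, and terms were not tested on these. Fisher's test also takes genes as independent, so its p-values make no allowance for correlation between genes. The smallest p-values in the first group were those of integral component of plasma membrane (51 genes of 218, 20.6 expected), extracellular space (55 of 292), calmodulin binding (23 of 82), myofibril (11 of 23) and muscle contraction (13 of 32). In the second group they were those of nucleosome (15 of 37, 2.04 expected, adjusted p = 4.27e-07), gluconeogenesis (10 of 21), nucleosome assembly (11 of 28), the glycolysis and gluconeogenesis pathway (12 of 39) and glycolytic process (7 of 13).

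**Figure D4:**
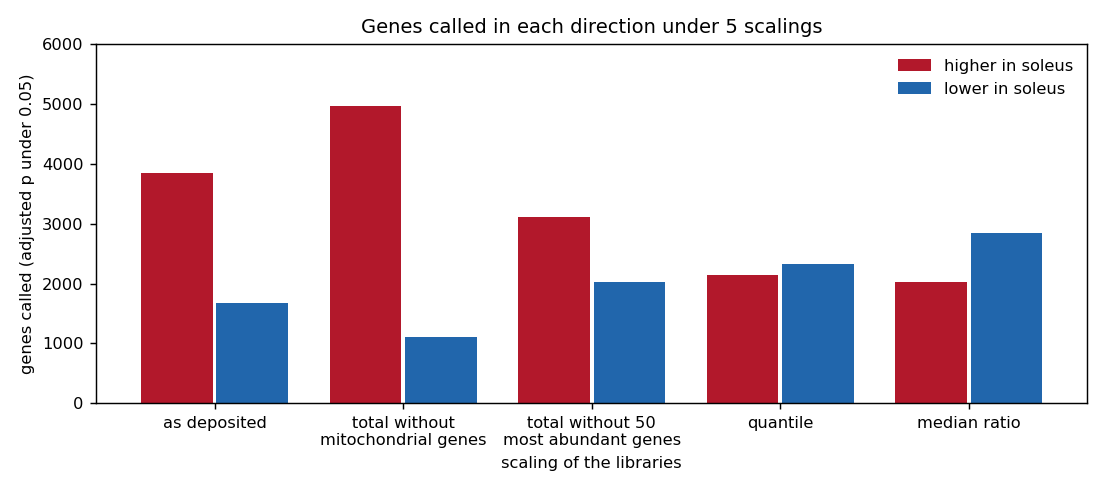
Bars give the number of genes called higher (red) and lower (blue) in soleus by limma under 5 scalings of the libraries. As deposited, 3844 were higher and 1670 lower, and under median-ratio scaling 2026 and 2837.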

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

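The scaling to the total without mitochondrially encoded genes and the voom fit were chosen after the data were seen. No gene called as reported was called in the opposite direction under any of these settings, but the number of calls moved, and the cause was not tested unless stated. With a mean FPKM of at least 5, where 5099 genes were tested, 1639 were higher and 1321 lower, so the share higher fell from 69.7% to 55.4%. Genes higher in soleus numbered 2026 under median-ratio scaling and 2147 under quantile normalization, and genes lower in soleus 2837 under median-ratio scaling and 1112 with mitochondrially encoded genes left out. Genes at least 2-fold higher numbered 1659 with a pseudocount of 0.1, 550 with a mean FPKM of at least 5, 494 under median-ratio scaling, 586 under quantile normalization, 1451 without mitochondrially encoded genes and 1781 with voom, and genes at least 2-fold lower 1039 under median-ratio scaling. Of 5514 calls, 3696 were kept under median-ratio scaling. Leaving out 1 library gave 3157 to 3597 genes higher and 1311 to 1678 lower, 860 to 1026 at least 2-fold higher and 513 to 589 at least 2-fold lower. The first component held 79.4% of the variance with no filter, 85.6% with a mean FPKM of at least 5 and 82.8% to 85.2% with 1 library left out. With an estimated inter-gene correlation, camera called 0 lists against 14 (3 at an unadjusted p under 0.05; fry, which tests against no change, called 20), and leaving out 1 library gave 11 to 15 lists. Terms numbered 49, and 27 with calls limited at once to an adjusted p under 0.01 and at least a 4-fold difference, and they were not tested under another scaling.

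With the replicate number as a block, 4207 genes were higher and 1873 lower, and apart from the calls named beside the results (the fast contractile, extracellular matrix and smooth muscle lists, ANKRD1 and SPARC) it changed no other call of a list or named gene. Of 145 named genes under 2300 gene and setting pairs, 2216 kept their direction and side of the threshold, 56 lost the call and 13 gained it. Among the genes of the lists, calls were lost under median-ratio scaling for AMPD2, ATP5B, CSAD, PMP22, SPRY1, SQSTM1, TAGLN and VWF, under quantile normalization for AMPD2, CKMT2, CSAD, SPRY1 and TAGLN, without the 50 most abundant genes for TAGLN, with no filter for CKMT2, MYH1A, NID1, NR4A3, TAGLN and UQCR10, and with mitochondrially encoded genes left out for CKMT2, FBXO40, HSPA8, PSMB5 and UQCR10. Another 15 changed sign, all but MCM2 in genes not called as reported. Under median-ratio scaling these were CASQ2 (-0.17), HBA1 (-0.0956), HES1 (-0.31), HSPB1 (-0.29) and PCNA (-0.27), without the 50 most abundant genes HES1 (-0.075), HSPB1 (-0.0335) and PCNA (-0.0215), under quantile normalization CASQ2 (-0.0085) and MCM2 (-0.0119), and without mitochondrially encoded genes MDH2 (0.17). With 1 library left out, HES1 ranged from -0.46 to 0.47 (below 0 without pectoralis major library 1, and at -0.19 without soleus library 3), HSPB1 from -0.0891 (without soleus library 2) to 0.24 and MYH1D from -0.29 (without pectoralis major library 2) to 1.26. Genes of few fragments are limited by depth, since 1 fragment per kilobase was worth 0.0256 to 0.0275 FPKM.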

Other observations

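Genes in this part outside the lists, and all tests in it except that of gene length in its wider range, were chosen after the results were seen. The non-coding gene LOC107055410 had 75.5, 116.04 and 120.4 FPKM in the soleus libraries and was listed at 0, 0.0808 and 0 in pectoralis major (limma log2 difference 6.65, adjusted p = 8.09e-08). Below the filter, MYH7, the slow myosin heavy chain of heart and slow muscle, had 7.17 FPKM in soleus library 1 and 0.337 and 0.419 in libraries 2 and 3. Pectoralis major library 3 had 10.4 FPKM of MYH13, where the other 5 libraries had 0.286 to 0.752, and 74.9 FPKM of MYH1A, where the other pectoralis major libraries had 3.70 and 1.58.

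The nucleosome genes that were at least 2-fold lower in soleus numbered 15, with a median log2 difference of -1.51. HIST1H111R, a linker histone, had 0.773 ± 0.117 FPKM in soleus and 30.3 ± 21.3 in pectoralis major. Gene length argues against a length bias: 5042 other genes of the same lengths, 439 to 3475 bases, had a median of 0.19 ± 0.02 (SE), and a narrower range up to 1561 bases, added because 1 long gene widened the first, gave 0.15 ± 0.03. More dividing cells in pectoralis major stays open. The 6 tested genes of replication and mitosis had a median of -0.0205 ± 0.18, above the bound of -0.75 set for this explanation. With a pseudocount of 0.1 their median was -0.09 ± 0.29, against -2.2 for the nucleosome genes. MCM2 was called higher and MCM5 lower in soleus, and neither call held in every setting. However, 5 of the 6 (MCM2, MCM5, MCM6, CCNA2 and CCNB1) had means of 0.901 to 2.45 FPKM, near the filter on low values. A requirement on their level, added after the values were seen, leaves the question undecided. PCNA (25.8 and 23.9 FPKM) has a level that would hide a small share of such cells. Capture of transcripts without a poly(A) tail also stays open, as does an untested difference between the muscles: the median of 19 replication-dependent histone genes was lower than that of 8 histone variant genes (difference of medians -1.002 ± 0.33), within 2 standard errors of the bound of -0.5 set for it.

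TNNC1 was lower in soleus by a log2 difference of -2.11, against 12 of the other slow contractile genes. Had fragments only passed from TNNC2 to TNNC1, they could lower TNNC1 no further than TNNC2 itself moved (-0.25). TNNC1 minus TNNC2 was -1.86 ± 0.14, which argues against that, and TNNC1 was the more abundant of the pair in pectoralis major. An exchange of fragments in both directions would also change the value of TNNC2. It is not bounded by that value and stays open, as the sequences were not compared. The authors' normalization is argued against as the whole cause, since the difference nearest to 0 under the other scalings was -1.88. A difference between the muscles in the use of this gene stays open as a hypothesis and was not tested otherwise.

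More genes were called higher than lower in soleus (69.7% of calls). Fragments taken by mitochondrially encoded genes are argued against as the cause, since these genes lower all others where they take more, and they took 21.2 ± 2.19% of fragments in soleus and 7.96 ± 0.838% in pectoralis major (SD), a difference of 13.2 ± 1.35 percentage points (SE). The authors' normalization to the library total cannot be told apart from a true difference in the number of active genes between the muscles, which was not tested. The share was 41.7% under median-ratio scaling and 48.1% under quantile normalization, but these scalings centre the genes (median log2 difference -0.04 and -0.003), which by itself brings the share near even.

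The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. In 1 of the 10 splits, the real one, 5514 genes were called by limma, and the highest of the other 9 was 0 (153 at an unadjusted p under 0.05, against 6023). Each of the other splits puts libraries of both muscles in both groups, so the difference between muscles adds to the spread within groups. Low gene counts follow from this, and they do not show what chance alone would give. At least 2-fold calls numbered 1437 in the real split and at most 0 in the others. Called lists numbered 14 in the real split and at most 13 in the others, and at most 11 in the 3 other splits that part all pairs of equal number. The other splits hold unequal numbers of a muscle's libraries in their groups, so part of the muscle difference stays between the groups. Lists may be called from that part, so these list counts do not show what chance alone would give either.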
